A study of Homo sapiens with 6 samples.

How the data were processed

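The series holds 6 samples of HCT116 cells, 3 wild type and 3 with the p53 responsive element of the PURPL promoter deleted, grouped by the genotype and replicate number in the labels. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns with DNase I treatment, turned into biotinylated cRNA and hybridised to Illumina arrays. The deposited intensity values are mean bead signals per probe, exported without normalization by GenomeStudio version 1.9.0, per the file headers. The deposited detection p-value of each probe, per the file headers from the same export, moves in steps set by the 770 negative-control probes of its array. A deposited table of log2 values gives the authors' processed data, and how it was made is not given in the sources used here. Its ranks match each sample's own intensities (rank correlation 1), its median is 5.12 or 5.13 and its range 0.014 to 14.802 on each array. The equal ranges point to quantile normalization between arrays, while the background correction behind the table stays unknown.

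From the intensities, background was corrected with limma's neqc (normexp fitted on the negative controls, offset 16) followed by quantile normalization and log2, in limma 3.58.1 under R 4.3.3. The negative-control, housekeeping and spike-in probes were then left out. Probes were named through the gene ID (35663) or accession (85) in the human RefSeq table for GRCh38.p14, used for names and gene order alone, and 11471 kept the name in the file. A probe was tested if its detection p was under 0.05 on at least 3 arrays, which 17574 probes met. Of several such probes of a gene the brightest stood for the gene, giving 13713 genes, of which 3147 had over 1 detected probe. Names in the text follow the RefSeq table, and values of other detected probes are given where they differ in sign and for some further genes.

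The contrast was fitted with lmFit and eBayes, group alone in the model, with Benjamini-Hochberg adjustment and a threshold of 0.05. An adjusted p for a gene comes from this fit unless another setting is named, and a log2 change is knockout minus wild type with its moderated standard error. For a gene whose probes were detected on no array of a group, the change is given as a bound, which holds under the main background correction alone. The bound sets the mean of the other group against the mean, over the dim arrays, of the higher of the probe's value and the lowest detected value of that array (4.97 to 5.37). PURPL was fitted among all 47219 probes, since its probes did not meet the filter.

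The design, the alternatives, the rule for named genes and 26 gene lists were fixed before the data were examined. The rule took PURPL, MDM2, CDKN1A, MYBBP1A, ELAVL1 and a gene that is not reported here, then the 10 highest and 10 lowest log2 changes among called genes with non-overlapping groups and a regular symbol. It also took up to 4 members with the smallest adjusted p of each list. The lists cover p53 targets and regulators, cell cycle, ribosome, energy, stress, interferon, inflammatory, WNT, TGF-beta, NRF2 and apoptosis genes, epithelial, mesenchymal, leukocyte and intestinal markers, and reference genes. Lists with at least 5 tested members (25) were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. At an estimated correlation camera uses the few residual degrees of freedom of the 6 arrays, and at a preset one the number of tested genes. Its p can therefore be higher at an estimated correlation even where the estimate lies below the preset one.

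The fit was tested on simulated data made from the means and residual spread of the 13713 genes for knockout against wild type, with 200 genes changed. It recovered 0% of log2 changes of 0.5, 22% of those of 1, 84% of those of 2 and 90% of those of 3, and called 6 unchanged genes among 104 calls. In a second simulation over the same genes a list of 51 members shifted by 0.3 was called and 0 of the other lists were. Both simulations drew each gene independently, with the same spread in both groups. They therefore do not test how the list calls depend on correlation between genes.

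Alternatives were the replicate number as a block, each array left out, no background correction, an offset of 50, median scaling, the deposited log2 table, no detection filter, a filter at p under 0.01 on all arrays of a group, array weights, a trended and robust prior (statmod 1.5.0), the mean of probes, every probe alone, stricter thresholds and the estimated correlation. All 6 arrays sat on 1 BeadChip, so a chip block could not be fitted. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

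Detected probes numbered 18615, 17759 and 18181 on wild type 1 to 3 and 19347, 15643 and 17003 on knockout 1 to 3. The median SD of a tested gene was 0.18 (log2) among wild type and 0.30 among knockout arrays, and the median standard error of a log2 change was 0.22. The median change over all tested genes was -0.03.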

Results

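Gene expression was measured in HCT116 cells, an established human colorectal carcinoma line. The knockout cells lacked the p53 responsive element in the promoter of PURPL, a long noncoding RNA gene whose transcription p53 induces. Total RNA of 3 wild type and 3 knockout samples was hybridised to 6 single-colour Illumina bead arrays, each with 47219 probes for human transcripts. The series set out to find genes regulated by PURPL, and its only contrast is knockout against wild type. Between 15643 probes (knockout 2) and 19347 probes (knockout 1) gave signal above the negative controls at a detection p under 0.05. Knockout 2 stood apart from the other arrays. Its mean correlation with the other knockout arrays across genes was 0.966, and its 6 bright housekeeping probes averaged 5746 intensity units. The same average was 9873 on knockout 3 and 20181 on wild type 2, the next lowest and the highest of the other arrays. The labels do not say that the replicates came from separate cultures or clones, so each p-value measures only the spread between these samples, which may be technical, and the number of arrays, 3 per group, limits the precision. The labels name no drug, but a word in the header of the scanner export may point to one, so whether the cells were treated is not settled here.

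PURPL itself was not measurable on these arrays in either group. Of its 18 values (3 probes on 6 arrays), 1 had a detection p under 0.05, and it came from a knockout array. The array lists the 3 probes under LOC643401, between positions 27511400 and 27520841 of chromosome 5, with a genome build that is not given in the sources used here. The brightest probe averaged 4.80 ± 0.20 (log2, SD, n = 3) in wild type and 4.63 ± 0.12 (n = 3) in knockout cells. In the limma fit its difference of -0.17 ± 0.14 (SE) had an adjusted p of 0.783, and the other probes differed by -0.06 and 0.24, with adjusted p of 0.941 and 0.838. With both groups at background no fold change is given, and the probes do not check which samples carry the deletion.

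The other genes named in advance, MDM2, CDKN1A, MYBBP1A and ELAVL1, did not pass the test between the groups. MDM2, a ubiquitin ligase, differed by -0.12 ± 0.35 (log2 knockout minus wild type, SE, limma adjusted p = 0.899). CDKN1A, which encodes the cell cycle inhibitor p21, was at 12.09 ± 0.16 (SD, n = 3) in wild type and 12.67 ± 0.26 (n = 3) in knockout cells. All 3 of its knockout values lay above the wild type values, and the difference of 0.58 ± 0.20 (SE) had an adjusted p of 0.188. A second CDKN1A probe differed by 0.19. MYBBP1A, a nucleolar protein that binds p53, differed by -0.39 ± 0.22 (adjusted p = 0.416), and ELAVL1, which encodes the RNA-binding protein HuR, by 0.12 ± 0.19 (adjusted p = 0.795). MDM2 and MYBBP1A were each detected on 2 of the 3 knockout arrays.

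**Figure D1:**
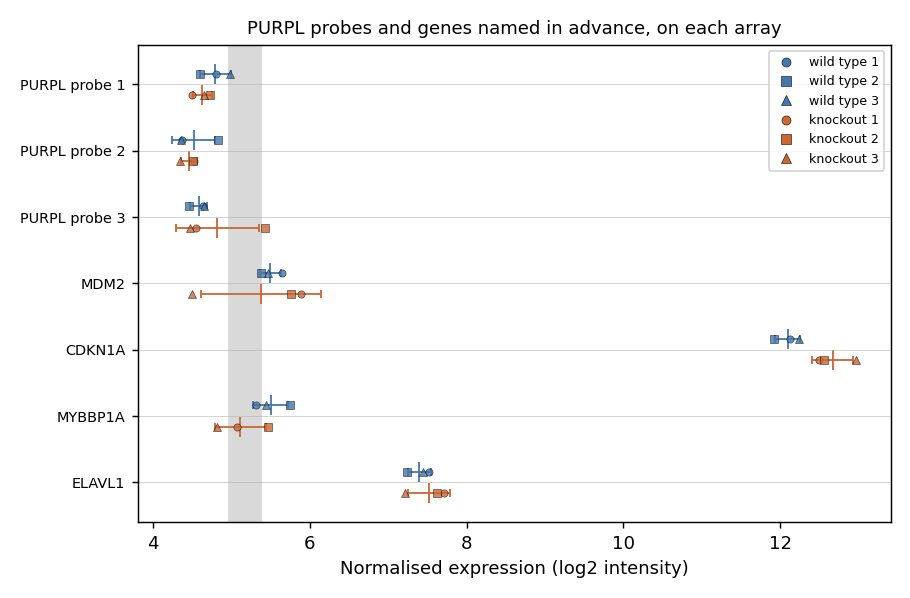
Normalised log2 intensity (x axis) of the 3 PURPL probes and of MDM2, CDKN1A, MYBBP1A and ELAVL1, with a symbol per array, a vertical tick at each group mean and a bar of 1 SD. The grey band spans the lowest detected value of each of the 6 arrays.

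Knockout cells expressed several genes that wild type cells did not show above background. SEMA3A, a secreted axon guidance protein, was detected on all 3 knockout arrays and on no wild type array, and was at least 14.9-fold higher in knockout cells (limma adjusted p = 5.84e-05). STXBP6, a SNARE-binding protein, was at least 6.72-fold higher, TNFSF4 (the OX40 ligand) at least 3.86-fold, DTNA (alpha-dystrobrevin) at least 3.51-fold and ZBED2 at least 2.48-fold. These bounds set the mean of the detected group against the lowest detected value of each array of the other group. In the opposite direction ADGRF1, an adhesion G protein-coupled receptor listed as GPR110, fell from 10.04 ± 0.13 (log2, SD, n = 3) to 4.95 ± 0.37 (n = 3), with detection on 1 of 3 knockout arrays, and its other probes differed by -4.04 and -2.97. PDE4B, a cAMP phosphodiesterase, went from 9.78 to 5.86 (log2), with -2.67 at its other probe, and EMP1, a small membrane protein of epithelia, differed by -3.44. The bounds hold only under the main background correction. Without it the log2 change was 2.08 for SEMA3A, 1.26 for STXBP6, 0.84 for TNFSF4, 0.71 for DTNA and 0.70 for ZBED2. Each of these is smaller than the bound given above. PDE4B and EMP1, which have no bound, changed by -2.37 and -2.15 without it, and the median called gene kept 50.4% of its log2 change.

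In total, limma called 242 of 13713 tested genes at an adjusted p under 0.05, 107 higher and 135 lower in knockout cells. In 212 of these the log2 change was at least 1 in size, and the smallest was 0.78. Of the called genes 13 were detected on no wild type array and 13 on no knockout array. In every called gene the 3 knockout values did not overlap the 3 wild type values, which held for 24.5% of all tested genes against 10% by chance. Further rises included PXDN, a matrix peroxidase (2.40 ± 0.35, log2, SE), HMSD (2.23 ± 0.24), MAP1B, a microtubule-associated protein (2.05 ± 0.24), JARID2, a subunit of Polycomb repressive complex PRC2 (2.00 ± 0.24), and AXIN2, a feedback inhibitor of WNT signalling (1.99 ± 0.21). HTR7, a serotonin receptor, and HKDC1, a hexokinase family member, were detected on all wild type arrays and on no knockout array, and were at least 5.25-fold and at least 5.42-fold lower in knockout cells. Without background correction their log2 changes were -1.19 and -1.11, smaller in size than these bounds. Further falls included the antisense transcript listed as SLC22A18AS, now SLC67A1-AS (-3.00 ± 0.16) and CYSRT1 (-2.66 ± 0.25). The noncoding VHRT, at 7.93 in wild type, the antiviral protein BST2, at 7.91, and PROM2, at 7.57, were near background in knockout cells, so no size is given for them. PROM2 was detected on 1 of the 3 knockout arrays, and PDE4B, VHRT and BST2 on 2 each.

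Of the 20 genes named so far as called, 16 remained called when any single array was left out. PXDN lost its call without wild type 1, 2 or 3 (highest adjusted p = 0.082), MAP1B and JARID2 without wild type 2 (0.0514 and 0.0553), and ZBED2 when any array other than knockout 2 was left out (highest 0.12). With median scaling HKDC1 had an adjusted p of 0.0528. The count of called genes was 56, 52 and 52 without wild type 1, 2 and 3 in turn, 177 without knockout 1, 241 without knockout 2 and 111 without knockout 3. Of the 241 genes called without knockout 2, 190 were among the 242.

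**Figure D2:**
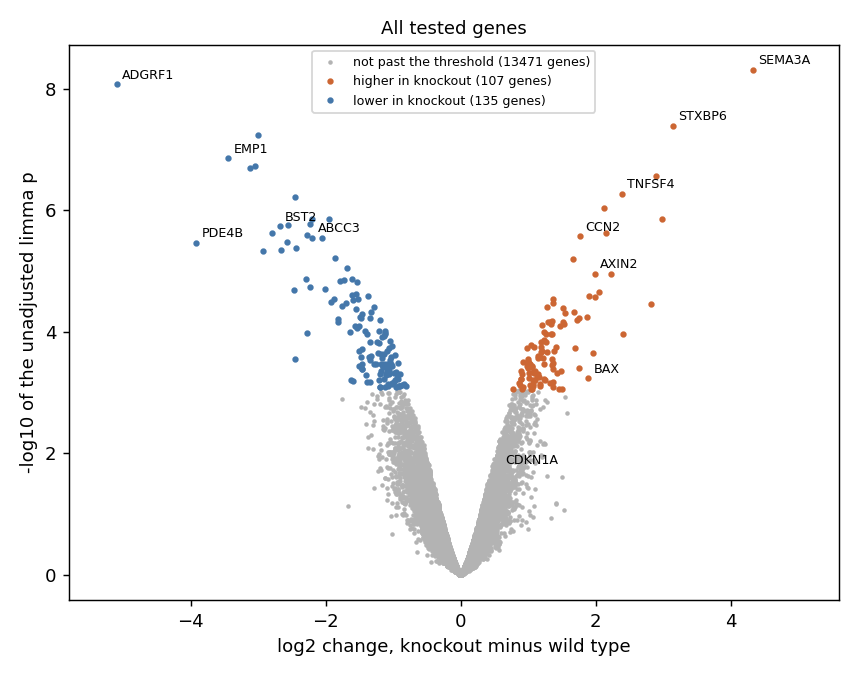
The log2 change (x axis, knockout minus wild type) of the 13713 tested genes against -log10 of the unadjusted limma p (y axis). Coloured points are the 107 genes higher and the 135 genes lower in knockout cells at an adjusted p under 0.05; SEMA3A and ADGRF1 lie farthest out, and CDKN1A lies among the genes that did not pass.

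**Figure D3:**
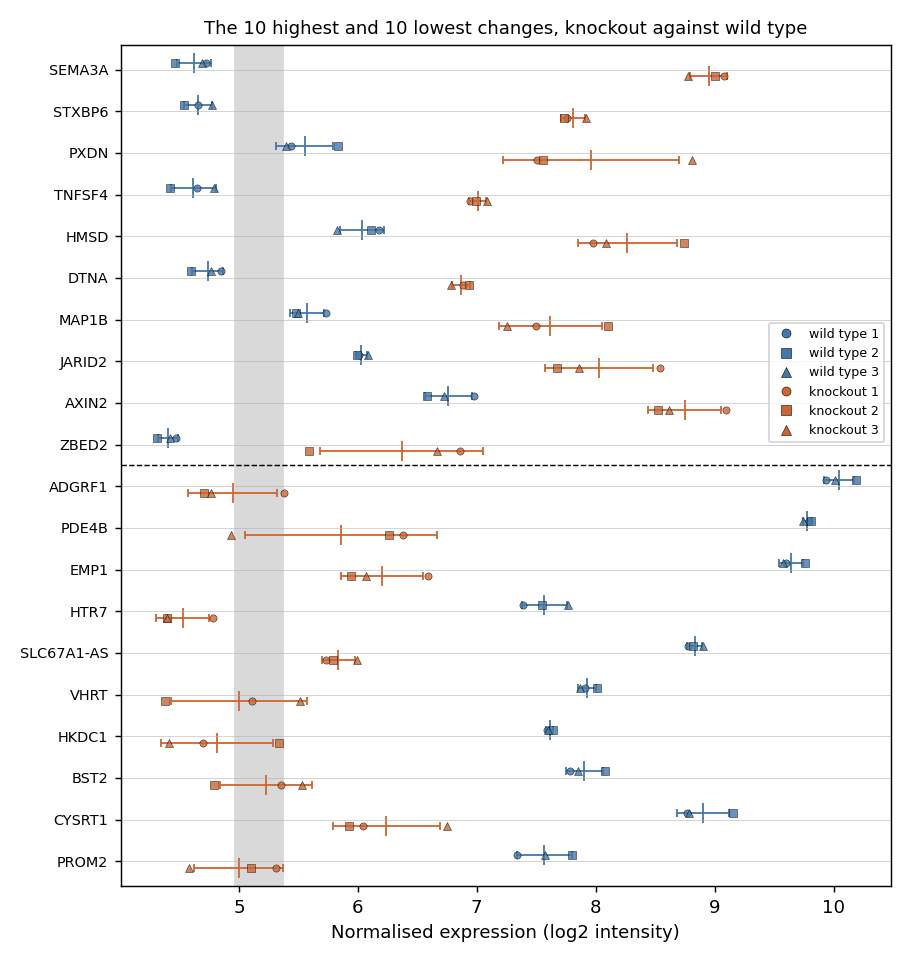
Normalised log2 intensity (x axis) on each array of the 10 genes with the highest (above the dashed line) and the 10 with the lowest log2 change, among called genes with a regular symbol. Ticks are group means, bars 1 SD (n = 3), and the grey band spans the lowest detected value of each array; the 3 arrays of a group lie on the same side of the other group for every gene.

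Several WNT target genes were higher in knockout cells, but the list passed camera only at the preset correlation (adjusted p = 0.00894; 0.19 with an estimated one), with 8 of 14 tested members positive. Of 23 listed genes 14 were tested, 4 rose and 0 fell over all genes tested, and 6 rose and 1 fell adjusted over the list alone. AXIN2 rose 3.96-fold, BMP4, a bone morphogenetic protein, 2.28-fold (1.19 ± 0.18, log2, SE), and DKK1, a secreted WNT antagonist, 2.01-fold (1.01 ± 0.17). NOTUM, a secreted WNT deacylase, was detected on no wild type array and was at least 1.62-fold higher. Its log2 change was 0.31 without background correction and 0.57 with an offset of 50, both smaller than this bound. The median member differed by 0.44 (0.15 to 0.47 over all refits, the lowest with no detection filter). After each list's median its range over all refits is given likewise. AXIN2 stayed called with each array left out, whereas BMP4, DKK1 and NOTUM lost their calls without wild type 1, 2 or 3 or knockout 3 (DKK1 also without knockout 1), with highest adjusted p of 0.114, 0.166 and 0.182. NOTUM kept its call in 3 of 9 other settings. With detection at p under 0.01 on all arrays of a group the adjusted p of the list was 0.0621.

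Known p53 targets passed camera upward at the preset correlation (adjusted p = 0.0199), but not with an estimated correlation (0.19) or with median scaling (0.128), and 47 of 51 tested targets did not pass singly. Among the targets 3 rose and 1 fell over all genes tested, 5 rose and 1 fell adjusted over the list alone, and 32 had a positive log2 change. TP53INP1, a stress-induced regulator of autophagy and apoptosis, rose by 1.00 ± 0.18 (log2, SE, adjusted p = 0.0329), BAX, a pro-apoptotic BCL2 family protein, by 1.89 ± 0.35 (adjusted p = 0.0405), and SULF2, an extracellular sulfatase, by 1.33 ± 0.25 (adjusted p = 0.0442). TNFRSF6B, a decoy receptor for FAS ligand, fell 4.72-fold (-2.24 ± 0.19, adjusted p = 0.00149), and its other 2 detected probes differed by -2.16 and -1.98. Second probes differed by 0.76 for TP53INP1, 0.57 for BAX and 0.0017 for SULF2. The median was 0.14 (0.07 to 0.22, lowest without background correction and highest with median scaling). TP53INP1 and SULF2 lost their calls with any single array left out and BAX with any but knockout 1 (highest adjusted p 0.182, 0.191 and 0.149). Of 18 tested p53 pathway regulators 0 passed, also adjusted over the list alone. Their median was -0.13 (-0.24 to -0.05, camera adjusted p = 0.398), and CDKN2A, which encodes p16 and ARF, differed by -1.08 ± 0.32 (adjusted p = 0.151), with -0.10 at its second probe.

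Genes of G2/M and mitosis passed camera upward at the preset correlation (adjusted p = 0.00894, median 0.16, -0.02 to 0.18), but not with an estimated correlation (0.19), and with median scaling the median was -0.02 (adjusted p = 0.946). None of the 40 tested members passed over all genes, and 1 was higher adjusted over the list alone, yet 33 of 40 had a positive log2 change. The kinetochore gene NUF2 differed by 0.81 ± 0.16 (log2, SE, adjusted p = 0.0527) and TOP2A, a DNA topoisomerase, by 0.85 ± 0.20 (adjusted p = 0.0828). For G1/S and DNA replication genes 0 of 39 passed by either adjustment, and the median was -0.00029 (-0.16 to 0.03, camera adjusted p = 0.788). UHRF1 differed there by 0.76 ± 0.21 (adjusted p = 0.133).

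Ribosome biogenesis and MYC-linked genes passed camera downward at the preset correlation (adjusted p = 0.0199, median -0.20, -0.32 to -0.12), but not with an estimated correlation (0.276). The call also ended without knockout 1 (0.169), knockout 3 (0.124) or wild type 3 (0.12) and with the stricter detection filter (0.054). Of 36 tested members 0 passed over all genes and 4 were lower adjusted over the list alone, among them CAD, an enzyme of pyrimidine synthesis, at 7.78 (log2) in wild type and 6.78 in knockout cells (adjusted p = 0.076). POLR1C, a polymerase subunit, differed by -0.68 ± 0.18 (log2, SE) and RRS1, a ribosome assembly factor, by -0.71 ± 0.19 (adjusted p of 0.116 and 0.118). Cytosolic ribosomal proteins (0 of 39 called by either adjustment, median -0.04, -0.05 to 0.06, camera adjusted p = 0.788) and oxidative phosphorylation genes (0 of 39, median -0.07, -0.20 to -0.03, adjusted p = 0.431) did not pass, though the latter had an adjusted p of 0.00641 with median scaling.

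Epithelial genes included 3 falls and 0 rises among 24 tested members, by either adjustment, the second taken adjusted over the list alone. These were ELF3, an epithelial transcription factor (-1.24 ± 0.19, log2, SE), and the tight junction genes TJP3 (-1.48 ± 0.24) and CLDN3 (-1.34 ± 0.25). The median was -0.14 (-0.25 to -0.11, lowest without wild type 2) and camera's adjusted p was 0.0781, or 0.276 with an estimated correlation. At the preset correlation it was 0.0315 without knockout 2, 0.028 without wild type 2, 0.0119 with median scaling, 0.0208 with array weights, 0.0487 with the trended and robust prior and 0.00271 with no detection filter. ELF3, TJP3 and CLDN3 each lost their calls without wild type 1, 2 or 3 or knockout 1, and the latter pair also without knockout 3 (highest adjusted p 0.109, 0.138 and 0.18). None of the 11 tested mesenchymal and stromal markers passed by either adjustment (median -0.28, -0.28 to 0.0015, camera adjusted p = 0.727), with VIM at 0.58 ± 0.16 (adjusted p = 0.123).

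Interferon response genes moved both ways. Of 31 tested members 1 rose and 4 fell over all genes, and 3 rose and 5 fell adjusted over the list alone. BST2 went from 7.91 to 5.23 (log2, wild type to knockout) and IFIT2 from 6.96 to 5.46, each detected on 2 of the 3 knockout arrays, and IFI27, detected on 1, from 6.20 to 4.87, while USP18, an ISG15 protease, rose 2.15-fold. The median was -0.10 (-0.20 to -0.04, camera adjusted p = 0.467). BST2 kept its call with each array left out. IFI27 lost its call without wild type 1, 2 or 3, without background correction (-0.39, adjusted p = 0.0564) and with median scaling (-0.75, adjusted p = 0.329). Single omissions ended the call of IFIT2 when any array but knockout 1 was left out, and of USP18 with any array left out (highest adjusted p 0.0753 for IFI27, 0.152 and 0.189).

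NRF2 targets included 3 falls and 0 rises among 19 tested members, and the same counts adjusted over the list alone. The efflux transporter ABCC2 went from 8.46 to 6.01 (log2), ABCC3 fell 4.58-fold, and FTH1, the ferritin heavy chain, fell 2.03-fold, with a median of -0.17 for the list (-0.26 to -0.11, camera adjusted p = 0.21; adjusted p = 0.0338 with median scaling). ABCC2 was detected on 2 of the 3 knockout arrays. ABCC3 kept its call with each array left out, and ABCC2 and FTH1 lost theirs without wild type 1, 2 or 3 or knockout 3 (highest adjusted p 0.127 and 0.144). Of 15 tested TGF-beta response genes 2 rose and 0 fell, and 3 rose and 3 fell adjusted over the list alone. These were the matricellular genes CCN2 (3.41-fold) and CCN1 (2.65-fold), and the list's median was -0.19 (-0.27 to 0.02, camera adjusted p = 0.881). CCN2 kept its call with each array left out, while CCN1 lost it without wild type 1, 2 or 3 or knockout 1 (highest adjusted p 0.119).

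Smaller numbers of calls fell in other lists. Among immediate early genes EGR1, a growth-factor-induced transcription factor, rose 2.87-fold as the single call of 25, with 4 rises and 0 falls adjusted over the list alone (median 0.04, -0.10 to 0.15, camera adjusted p = 0.316). EGR1 lost its call without wild type 1, 2 or 3 (highest adjusted p 0.0812). The chemokine CXCL8 fell 2.13-fold as the single call of 12 NF-kB and inflammatory genes by either adjustment (median -0.12, -0.18 to 0.02, adjusted p = 0.619). PFKFB4, a regulator of glycolysis, fell 2.02-fold as the single call of 32 glycolysis and hypoxia genes, of which 3 rose and 5 fell adjusted over the list alone (median -0.19, -0.21 to -0.10, adjusted p = 0.316; adjusted p = 0.0189 with median scaling). Of 7 tested intestinal differentiation and secretory genes, DPP4, a brush border peptidase, was at least 2.27-fold lower, detected on no knockout array, and CA2, a carbonic anhydrase, rose 1.88-fold; 2 rose and 3 fell adjusted over the list alone (median -0.12, -0.44 to -0.0033, adjusted p = 0.788). The log2 change of DPP4 was -0.45 without background correction and -0.98 with median scaling, both smaller in size than its bound. CXCL8 lost its call without wild type 1, 2 or 3 or knockout 3, PFKFB4 with any array left out, DPP4 without wild type 1 or 2 or knockout 1 or 3, and CA2 when any array but knockout 2 was left out (highest adjusted p 0.169, 0.186, 0.1 and 0.221). BAX was the single rise among 27 apoptosis regulators by either adjustment (median -0.04, -0.10 to 0.02, adjusted p = 0.508).

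Of 31 unfolded protein and integrated stress response genes 0 passed by either adjustment (median 0.10, 0.00068 to 0.18, camera adjusted p = 0.169; adjusted p = 0.0315 without knockout 2). No single call by either adjustment held also for 17 heat shock genes (median 0.03, -0.03 to 0.08, adjusted p = 0.542), 24 sterol biosynthesis genes (0.04, -0.14 to 0.05, adjusted p = 0.854), 13 histone genes (0.11, 0.04 to 0.18, adjusted p = 0.491) and 20 reference genes (-0.06, -0.13 to 0.0062, adjusted p = 0.788). Of 8 metallothionein genes 0 passed, and 1 was higher adjusted over the list alone (median 0.15, -0.04 to 0.36, lowest without knockout 2 and highest without knockout 1, adjusted p = 0.33). Of 30 autophagy and lysosome genes 0 passed, and CTSB, a lysosomal protease at -0.82 ± 0.18 (log2, SE), was the 1 lower adjusted over the list alone (median -0.07, -0.14 to -0.008, adjusted p = 0.754). Only 4 leukocyte and endothelial markers were tested, too few for camera. None passed over all genes, and CD68, a lysosomal protein that macrophages express highly, was the 1 lower adjusted over the list alone (-0.74 ± 0.20, adjusted p = 0.112 over all genes).

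Calls of named genes also ended under settings other than an omitted array. Median scaling ended those of HKDC1, TP53INP1, BAX, SULF2, PFKFB4, IFI27, IFIT2, USP18, CXCL8, BMP4, DKK1, NOTUM, CLDN3, DPP4 and CA2. With no detection filter they ended for PXDN, ZBED2, BAX, SULF2, PFKFB4, IFIT2, USP18, CXCL8, NOTUM, TJP3, CLDN3, DPP4, CA2 and ABCC2, and with the mean of probes for BAX, SULF2, CXCL8, NOTUM and CA2. IFI27, USP18, NOTUM and DPP4 lost them without background correction, NOTUM with an offset of 50 and USP18 with array weights. The replicate block ended those of TP53INP1, BAX, PFKFB4, IFIT2, USP18, CXCL8, BMP4, DKK1, NOTUM, ELF3, TJP3, CLDN3, DPP4, CA2, FTH1 and CCN1.

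With the preset correlation camera called 4 of 25 lists, and with an estimated correlation 0, though 3 had an unadjusted p under 0.05. The estimates for p53 targets (-0.0171), WNT targets (-0.0129) and G2/M genes (0.00428) lay below the preset 0.01. For ribosome biogenesis genes the estimate was 0.0153. Where the estimate lay below the preset value, the lost call came with fewer degrees of freedom and not with a stronger correlation. Without knockout 2 the preset-correlation adjusted p was 0.011 for WNT targets, 0.011 for G2/M genes, 0.0315 for p53 targets and 0.00144 for ribosome biogenesis genes. The fry test, which asks whether the genes of a list move on balance in the same direction without comparing them with other genes, called 7. These were p53 targets (adjusted p = 0.00224), WNT targets (0.0167), G2/M genes (0.0181), epithelial genes (0.0184), interferon response genes (0.0304), ribosome biogenesis genes (0.0369) and oxidative phosphorylation genes (0.0412). Median and camera direction differed in sign for the TGF-beta, autophagy, apoptosis and G1/S lists, each with a median below 0 and camera upward, and the sterol list had a mean of -0.02.

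**Figure D4:**
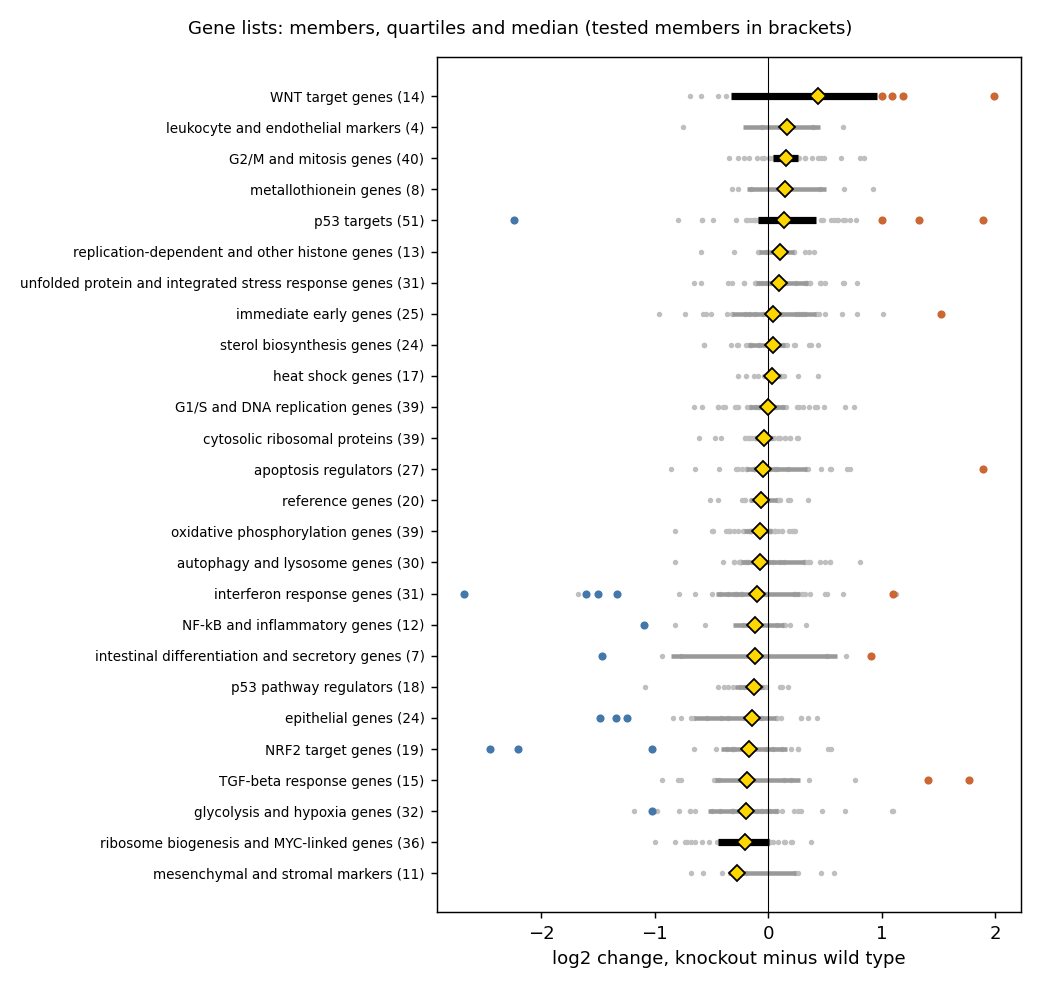
The log2 change (x axis, knockout minus wild type) of the tested members of the 26 lists. Bars span the quartiles, black for the 4 lists past camera's threshold, diamonds are medians, and larger coloured points are single genes with an adjusted p under 0.05 over all genes; WNT targets lie highest and mesenchymal markers, which camera did not call, lowest.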

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

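The 242 genes became 516 without background correction, 428 with an offset of 50, 520 with the trended and robust prior, 408 with the stricter detection filter, 155 without one, 141 with median scaling and 60 at an adjusted p under 0.01, and beyond the stricter threshold the cause was not tested. With fewer samples, leaving out each array gave 52 to 241. The replicate numbers showed at most weak pairing of the samples (correlations of same-numbered deviations 0.163, 0.0816 and 0.0022, with different-numbered ones not computed). The replicate block gave 94 genes, all among the 242. Each of the 242 kept its direction in every refit that tested it. Since the groups of each do not overlap, omitting an array, the replicate block or array weights could not reverse a direction. Only settings that change the values or the probes could. No named gene called here (43 genes, 686 values) reversed, and 158 of the values lost the call, while 67 values of the 82 named genes not called here gained it. Median scaling ended 15 named calls, no detection filter 14, the replicate block 16, the mean of probes 5 and no background correction 4 (IFI27, USP18, NOTUM and DPP4). Without a call in either setting, MDM2 reversed to 0.33 without knockout 3 (-0.37 to 0.33 over omitted arrays) and 0.40 with median scaling, LYZ to 0.036 without wild type 3 and 0.085 without knockout 1 (-0.13 to 0.085), and 0.23 with median scaling, MYBBP1A to 0.073 and H3C10 to 0.0091 with median scaling, and H2AC18 to -0.0839 with the mean of probes. The second probe of H2AC18 was at -0.493, against 0.33 for its brightest. PURPL, at background, reversed to 0.42 with median scaling (adjusted p = 0.631). The 4 lists past camera became 0 with an estimated correlation (medians, unmoved by it, 0.14 for p53 targets, 0.16 for G2/M, 0.44 for WNT targets and -0.20 for ribosome biogenesis) and 2 with the stricter filter, which lost WNT targets (0.37) and ribosome biogenesis (-0.17). Median scaling lost p53 targets (0.22) and reversed G2/M (-0.023), the cause not tested, yet raised the count to 6 with epithelial (adjusted p = 0.0119), oxidative phosphorylation (0.00641), glycolysis (0.0189) and NRF2 lists (0.0338). The unfolded protein list passed without knockout 2 (0.0315). With single arrays left out the ribosome biogenesis median ran from -0.26 to -0.16, its call lost without wild type 3, knockout 1 or knockout 3. A BeadChip block was not run, since 1 chip held all arrays. Low signal over background limits PURPL, MDM2 and MYBBP1A.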

Other observations

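The gene families of the next paragraph, the test of p53 targets without knockout 2 and the count over splits of the arrays were chosen after the results were seen, and the other tests before. For the tests on knockout 1 and knockout 2, reading an interval wholly above 50% as evidence against the explanation was also chosen after their values were seen.

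Families outside the fixed lists were picked because members stood out among the called genes. Their camera p-values re-use the genes behind the choice, so they are descriptive and not evidence for a family shift. Of 106 tested small nucleolar and Cajal body RNAs, guides of RNA modification, 5 rose and 0 fell. These were SCARNA11 (1.75 ± 0.31, log2, SE), SCARNA14 (1.5 ± 0.30), SNORD13 (1.48 ± 0.21), SNORA12 (1.35 ± 0.20) and SNORA67 (0.90 ± 0.17), and 74 of the 106 had a positive log2 change. The family median of 0.13 passed camera over the 4 families tried (adjusted p = 0.00148; adjusted p = 0.281 with an estimated correlation), and it ran from 0.05 without background correction to 0.43 with median scaling. Of 6 tested kallikrein-related peptidases, secreted serine proteases clustered on chromosome 19, KLK5 (-1.47 ± 0.20), KLK8 (-1.46 ± 0.19) and KLK7 (-1.13 ± 0.19) fell, KLK10 differed by -0.94 (0.19 at its second probe), and KLK3 and KLK6 by 0.29 and 0.52 without a call. The family passed camera (adjusted p = 0.00618; adjusted p = 0.0881 with an estimated correlation). Of 6 ABCC transporters 2 fell, ABCC2 and ABCC3, with the same adjusted p values. Among 258 genes named ZNF with a number, 2 rose and 3 fell, and the family did not pass (adjusted p = 0.131).

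The 242 called genes were set against technical explanations. The 6 arrays have 10 splits into 3 and 3, of which 1 gave as many genes, the real one, and the highest of the others gave 0, but so few splits cannot give a share under 0.05. Each other split mixes the groups, so any difference between the groups widens its spread and lowers its count. Lower signal in the knockout group as the main cause is argued against by knockout 1, which had the most detected probes of all arrays. It still lay nearer the other knockout arrays in 81.4% of the 177 genes called without it, short of the 90% set in advance and leaving 33 genes open. The 95% interval, 75.7 to 87.0, came from resampling the genes of this 1 array. Those genes are not independent, so the interval does not measure the spread between arrays. The median position of knockout 1 was 0.812 (0 at the wild type mean, 1 at that of the other knockout arrays). For knockout 2, with the fewest detected probes, it was 0.996, so a partial effect of signal stays open. Knockout 2, the array that stood apart, lay nearer the other knockout arrays in 86.7% of the 241 genes called without it, also short of 90% but far above the 50% a wild type sample could reach, and it detected all 15 of these genes that both other knockout arrays and no wild type array detected, which argues against a mislabelled wild type sample. The deletion itself and any difference between the cell lines or their handling that goes with the group stay open, untested.

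A candidate explanation for the upward shift of p53 targets is a higher p53 output in cells whose PURPL promoter lacks the p53 responsive element. These arrays test this hypothesis only through the targets, since PURPL was at background in both groups. A trend with probe GC content or brightness is argued against, since the log2 change had rank correlations of only -0.035 and 0.0558 with them across genes. With so little trend to remove, the test set in advance could hardly fail. The list kept 148% of its median (0.14 before, 0.20 after), which is not read as a stronger shift. The one-sided permutation p over genes, which are not independent replicates, was 6e-04 before and 5e-04 after. Knockout 2 alone is argued against as well, since without it the list still passed (adjusted p = 0.0315; 0.0107 to 0.128 over the other refits at the preset correlation, the highest with median scaling). With an estimated correlation the list did not pass camera (adjusted p = 0.19). The estimate itself was -0.0171 for the targets, below the preset 0.01, which argues against positive correlation among them as the reason. Camera with an estimated correlation uses the few residual degrees of freedom of the 6 arrays, which raises its p by itself. The shift stays open to clone differences. MDM2 and CDKN1A, at -0.12 and 0.58, did not pass by themselves. Among the targets that did, 3 rose and 1, TNFRSF6B, fell. G2/M genes also passed camera upward at the preset correlation (median 0.16, but -0.02 with median scaling). They were not used to test this hypothesis.

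Whether called genes lie beside each other was tested with 11895 placed genes. There were 5 adjacent pairs called in the same direction, all falling, where shuffled calls gave 2.14 on average and 5 at the 95th percentile (one-sided permutation p = 0.0651), so no excess was shown or excluded. The pairs, chosen by this test, were SLC67A1 with SLC67A1-AS, SLCO4A1 with SLCO4A1-AS1, KLK7 with KLK8, ADGRF1 with TNFRSF21 and MOK with ZNF839. The first 2 overlap, and 3 pairs were left without them against 1.95 by shuffling. A copy number difference cannot be told apart from local regulation, since the 49 uncalled genes within 5 positions differed by a median of 0.11 in the direction of the pair, with a 95% interval of -0.06 to 0.30 that reaches the 0.3 set in advance.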
